A study of Mus musculus with 18 samples.

How the data were processed

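Polyadenylated RNA of mouse bone marrow-derived macrophages was measured by 3′ end sequencing in 18 libraries, 12 in experiment 1 (4 groups of 3) and 6 in experiment 2 (2 groups of 3). Per the labels, RNA was reverse transcribed with barcoded oligo-dT primers, pooled by the level of Actb, amplified over 12 PCR cycles and sequenced in a strand-specific layout. The labels name STAR, HTSeq, DESeq2 and build mm10 without versions, and the gene annotation, the counting options and the sequencing read settings were not given in the sources used here. The deposited tables hold raw counts per gene with NCBI Entrez identifiers, which was checked on the values: they are whole numbers, every column has its own total, and no scaling was found. Each table lists 24052 genes, of which 23969 were matched to a symbol in the GRCm38 annotation and 83 were not; unmatched genes were tested but not named, and held at most 0.738% of the counts of a library in experiment 1 and 2.14% in experiment 2. No molecular identifiers are described, so counts include PCR copies, and counting intervals and floors cover counting error only. Since the strand option of the counting is not given, overlapping and antisense genes cannot be told apart, and reads of near-identical copies (Serpinb9b and Serpinb9, Tgtp2, Hspa1a and Hspa1b, Ifi205 and Ifi204, Erdr1, and genes with processed copies such as Prdx1 and Ftl1) are uncertain in their assignment.

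Depth per library, in replicate order, was 7010265, 2228760, 4367091 counts for vehicle, 6660270, 5233342, 7629669 for the compound, 3761119, 2294042, 955718 for LPS, 5959474, 4106831, 4032466 for compound plus LPS, 5153301, 3900554, 5491684 for the knockout and 3088644, 3244569, 4454025 for wild type. TMM factors lay between 0.576 and 1.47 in experiment 1 and between 0.967 and 1.05 in experiment 2. Correlations of log2 CPM between replicates lay between 0.934 and 0.971 outside the LPS group, where they were 0.908, 0.781 and 0.752. Common dispersion was 0.122 in experiment 1 and 0.0516 in experiment 2. On data simulated from these libraries, the test recovered 2.08% to 9% of genes changed 2-fold and 53.6% to 65.7% of genes changed 4-fold in the 2-group comparisons of experiment 1, and 0% and 8.25% for the interaction. In experiment 2 it recovered 19.6% and 80.8%, and 78.4% and 98.0% with a term for replicate number. False calls made up 0% to 5.70% of calls. The simulated data of experiment 2 were drawn from the fit with that term, so its gain there was built in. Those of experiment 1 used a single mean and spread per gene for all groups before changes were added. They lack the extra spread and the excess of genes at 0 of the LPS libraries.

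Each experiment was fitted with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group with a minimum count of 10, a quasi-likelihood negative binomial fit with a mean per group, and a 2-sided quasi-likelihood F test per contrast. After filtering, 10285 genes were tested in experiment 1 and 9491 in experiment 2, with 8 and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are edgeR estimates with a prior count of 0.125, and their standard errors are derived from the fit. For a gene at 0 in every library of a group, only a bound is given, computed against a floor of 3 counts over the group on TMM-scaled totals. The bound pools the counts of the other group, so it can differ from a ratio of mean CPM. For 1 to 3 counts in a group, the ratio is given with its counting interval on the same scale. The 6 comparisons were LPS against vehicle, compound against vehicle, compound plus LPS against LPS, compound plus LPS against compound, the interaction of compound and LPS, and knockout against wild type. P-values measure the spread between these samples, in experiment 1 estimated over all 4 groups together, and the LPS libraries varied more than the others. With only the 2 compared groups fitted, calls fell from 1636 to 653 (compound plus LPS against LPS) and from 3529 to 2108 (LPS against vehicle). They rose from 292 to 1013 (compound against vehicle) and from 1948 to 3196 (compound plus LPS against compound). P-values may thus be too small where the LPS group is compared and too large elsewhere. The labels do not say whether replicates come from separate animals or separate cultures. Pairing by replicate number was judged on correlations of deviations from the group mean. Same-numbered libraries in experiment 1 were not clearly paired over all groups (8 of 18 pairs correlated above 0.1). For compound plus LPS and LPS all 3 such pairs did (0.188 to 0.292), and a block gave 786 higher and 678 lower genes there, against 862 and 774. In experiment 2 all 3 pairs did, so it was also fitted with replicate number as a block, which leaves 2 residual degrees of freedom. The fit draws the spread of each gene toward that of all genes. Small p-values and standard errors with the block therefore rest largely on this shared spread, not on the 3 pairs of a gene alone.

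Groups of genes were tested through 33 lists, fixed from textbook knowledge: 21 of pathways and sex-linked genes, 9 of cell type markers and 3 of RNA quality. Pathway lists covered inflammatory cytokines, NF-kB feedback, Nfkbiz dependence, type I and gamma interferon, NRF2, ATF4, the unfolded protein response, heat shock, glycolysis, the TCA cycle, the respiratory chain, cholesterol synthesis, LXR, inflammasome, MHC class II, alternative activation, cell cycle, lysosome, itaconate and sex-linked genes. Cell type lists covered macrophages, neutrophils and progenitors, dendritic, B, T and NK, erythroid, mast, stromal and osteoclast cells, and quality lists covered mitochondrially encoded, ribosomal protein and housekeeping genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison, and its called members were counted over all genes and after adjustment over the list alone. None of the 13 mitochondrially encoded genes is in the tables, so that list was not tested. Lists share members, such as Slc7a11 in the NRF2 and ATF4 lists and Il6 in the cytokine and Nfkbiz lists. Their results are therefore not independent. Named genes followed a rule: the 8 genes with the largest increase and the 8 with the largest decrease (6 and 6 for the interaction, none for compound plus LPS against compound) among called genes at 5 CPM or more whose libraries did not overlap between groups, passing over unnamed transcripts; a panel of 16 genes; and up to 4 members per list with the smallest adjusted p. Comparisons, tests, lists, the naming rule and most alternatives were chosen before the data were examined; fits without LPS replicate 3 for lists and for comparisons that do not hold it, the block in experiment 2 alone, medians at bounds, and naming from the blocked fit were chosen afterwards.

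LPS-induced and LPS-repressed genes were counted by their call in compound plus LPS against LPS and set against the count for independent lists and 40 simulations with shared LPS libraries and no compound effect. Compound-responsive genes were tested in the knockout with camera, by overlap, and by Spearman correlation. Alternatives were DESeq2-type size factors, the Wald test of DESeq2 1.42.0, limma-voom, no count filter, a mean count of at least 20, robust spread, a replicate block, only the 2 compared groups in the fit, calls of at least 2-fold, and leaving out each library. Expected counts for the libraries came from the other libraries of a group: a gene was predicted at 10 or more counts, and libraries were thinned to 955718 counts in 10 draws. Positions were shuffled 10000 times for the test of neighbouring genes, and GC content was taken over the last 500 bases of transcripts. Reads were not used here. Some genes are withheld, and results that need them are not reported here, so the genes named are not all that passed.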

Results

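RNA of mouse bone marrow-derived macrophages from C57BL/6 animals was sequenced from the 3′ end of polyadenylated transcripts in 2 experiments. Marrow cells were matured with 20 ng/ml M-CSF, the growth factor that makes macrophages. In experiment 1, wild-type cells received 0.25 mM dimethyl itaconate, a membrane-permeable ester of the metabolite itaconate, or vehicle for 12 h, and then 100 ng/ml LPS, the bacterial lipopolysaccharide, for 4 h or no LPS. Its 4 groups of 3 libraries are called vehicle, compound, LPS and compound plus LPS. In experiment 2, 3 libraries of cells lacking Irg1 were compared with 3 of wild-type cells, all stimulated with 100 ng/ml LPS and 50 ng/ml interferon gamma for 24 h. Irg1 is listed under its current symbol Acod1 and encodes the enzyme that makes itaconate in macrophages. In the GRCm38 (mm10) build, key genes were Acod1 (Entrez gene 16365) on chromosome 14 from 103047012 to 103056573, Nos2 (Entrez gene 18126) on chromosome 11 from 78920787 to 78960226, Il6 (Entrez gene 16193) on chromosome 5 from 30013114 to 30019975, Il12b (Entrez gene 16160) on chromosome 11 from 44400063 to 44414677 and Il1b (Entrez gene 16176) on chromosome 2 from 129364569 to 129371164. Oxidant-defence genes named most often were Gclc (Entrez gene 14629) on chromosome 9 from 77754535 to 77794489, Nqo1 (Entrez gene 18104) on chromosome 8 from 107388225 to 107403205 and Slc7a11 (Entrez gene 26570) on chromosome 3 from 50364936 to 50499087.

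Total counts lay between 955718 and 7629669 per library in experiment 1 and between 3088644 and 5491684 in experiment 2. A gene at 0 in a whole group was set to a floor of 3 counts over that group, and in a single library 3 counts correspond to 0.393 to 3.14 CPM in a library of experiment 1 and to 0.546 to 0.971 CPM in experiment 2. Of the 6 libraries given LPS in experiment 1, the 3 without the compound were the least deep, at 3761119, 2294042 and 955718 counts. Among genes that the other libraries of their group predicted at 10 or more counts, 2.04%, 2.09% and 6.17% were at 0 in the LPS libraries, against 0.0892% to 0.326% in the other 9 libraries of experiment 1. LPS replicate 3 stood apart from the other LPS libraries: 17.6% of its counts came from Prdx1, a peroxiredoxin that removes hydrogen peroxide, against 3.81% and 3.28% in replicates 1 and 2. Prdx1 took 1.34% to 2.03% of the counts in vehicle libraries, 4.70% to 6.55% with the compound and 8.70% to 14.1% with compound plus LPS. Counts for ribosomal protein genes made up 3.33% to 3.76% in vehicle libraries, 2.58% to 2.67% with the compound, 1.51% to 1.94% with LPS and 1.77% to 2.04% with compound plus LPS. Fold changes are given on the log2 scale with their standard error, and levels are means of counts per library total scaled by TMM (CPM) ± SD over 3 libraries per group. Genes named from the 2-group comparisons as passing the test moved the same way in all 3 same-numbered library pairs, except where another number is given.

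LPS against vehicle asked how macrophages without the compound responded to the endotoxin. LPS raised 1641 and lowered 1888 of 10285 genes tested (1942 and 2084 without LPS replicate 3). Transcripts of cytokines and of inflammatory enzymes were among the largest increases: Nos2, the inducible nitric oxide synthase, was at least 1265-fold higher by pooled counts (adjusted p = 1.3e-06), with 0 counts in every vehicle library and 155 ± 98.4 CPM after LPS. Il6, a pyrogenic cytokine, was 2767-fold higher (log2 11.43 ± 0.77, adjusted p = 4.7e-09). Ptgs2, the inducible cyclooxygenase, was 1494-fold higher (log2 10.54 ± 0.74, adjusted p = 7.2e-09). Acod1 went from 13 ± 3.87 CPM to 14893 ± 7049 CPM, 1158-fold higher (log2 10.18 ± 0.68, adjusted p = 4.7e-09). Il1b rose 394-fold, Il12b 465-fold and Tnf 237-fold (adjusted p = 1.6e-08, 1.7e-08 and 6.4e-09). Mir155, the host transcript of an inflammatory microRNA, had 3 counts in the vehicle libraries against 1561 after LPS, a ratio with a counting interval of 647 to 9194. The nucleoside phosphorylase Upp1 and the costimulatory ligand Tnfsf4, at 0 in vehicle cells, were at least 437-fold and 184-fold higher (adjusted p = 8.0e-07 and 4.8e-06).

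All 5 immune lists rose as groups with LPS. Of inflammatory cytokines and chemokines 24 of 25 rose (24 adjusted over the list alone), with Ccl2 272-fold and Ccl5 359-fold higher (adjusted p = 4.7e-10 and 1.8e-09). Of NF-kB feedback genes and early regulators 26 of 28 rose (26 adjusted over the list alone), among them the costimulatory receptor Cd40, 456-fold, and the signalling inhibitor Socs3, 789.6-fold higher (adjusted p = 4.7e-10 and 5.2e-10). In the list that depends on the nuclear regulator Nfkbiz, 13 of 13 rose (13 adjusted over the list alone), and Nfkbiz itself was 17.8-fold higher (log2 4.15 ± 0.49, adjusted p = 3.7e-06). Of type I interferon response genes 35 of 36 rose (36 adjusted over the list alone), among them Ifi205 at 1019-fold and the antiviral gene Rsad2 at 298-fold (adjusted p = 4.7e-10 and 1.4e-09). Of interferon gamma response genes 26 of 27 rose (26 adjusted over the list alone), with the guanylate-binding protein Gbp5 549.6-fold and the chemokine Cxcl9 579-fold higher (adjusted p = 4.7e-10 and 2.0e-09). Their camera tests gave adjusted p = 8.9e-43, 8.8e-34, 8.0e-21, 5.7e-47 and 8.4e-42 in that order, and adjusted p of 0.0016, 0.00068, 0.00016, 0.0016 and 0.00016 with an estimated correlation. For inflammasome and pyroptosis genes 12 of 18 rose and 3 fell (12 and 3 adjusted over the list alone), with Nlrp3, the sensor that activates the inflammasome, 23.5-fold higher (camera adjusted p = 1.0e-08, and adjusted p = 0.017 with an estimated correlation).

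Metabolic genes moved in both directions with LPS. Among glycolysis and HIF-1 target genes 13 of 29 rose and 2 fell (13 and 2 adjusted over the list alone), including the glycolytic regulator Pfkfb3, 11.3-fold higher (log2 3.5 ± 0.41, adjusted p = 3.2e-06). The lactate exporter Slc16a3, 4.56-fold higher (adjusted p = 8.2e-05). The list rose as a group at the preset correlation (camera adjusted p = 0.025). That call was lost with an estimated correlation (adjusted p = 0.54). Hif1a itself was 3.90-fold higher (adjusted p = 0.0020), higher in 2 of 3 same-numbered pairs. In the itaconate and anaplerosis list 4 of 14 rose and 3 fell (4 and 3 adjusted over the list alone), with Irf1, a transcription factor of interferon signalling, 17.0-fold higher (adjusted p = 1.2e-08). Isocitrate dehydrogenase Idh1 was 4.12-fold lower (log2 -2.04 ± 0.27, adjusted p = 1.5e-05) in the TCA cycle list, where 4 of 27 fell (2 adjusted over the list alone). Sdha, the succinate dehydrogenase subunit that binds succinate, did not pass (log2 -0.78 ± 0.36, adjusted p = 0.10). NRF2 targets, which defend against oxidants, split: 8 of 37 rose and 6 fell (8 and 6 adjusted over the list alone), with a list median of 0.05. The member Slc7a11, which imports cystine, rose 18.0-fold (adjusted p = 3.1e-06). Prdx1 was 11.3-fold higher (adjusted p = 0.00039) with all libraries and had log2 1.98, adjusted p = 6.8e-05 without LPS replicate 3, in which it took 17.6% of the counts. In the LXR and cholesterol efflux list 4 of 11 fell (4 adjusted over the list alone), among them the cholesterol exporter Abca1 at 4.55-fold lower (adjusted p = 0.00062). Of lysosome and TFEB genes 9 of 29 fell (9 adjusted over the list alone), Tfeb at 6.27-fold lower (adjusted p = 0.0024). Neither list passed as a group (camera adjusted p = 0.33 and 0.086).

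The 8 decreases picked by rule, from fitted values, were genes with 0 counts in all 3 LPS libraries. Zfyve28 was at least 64.3-fold lower (adjusted p = 2.7e-06), the peroxisomal fatty acid transporter Abcd2 at least 58.5-fold lower (adjusted p = 6.5e-06). The Ras activator Rasgrp3 at least 51.8-fold lower (adjusted p = 6.9e-06). Dnmt1, the maintenance DNA methyltransferase, went from 21.9 ± 0.692 CPM to 0, at least 39.4-fold lower (adjusted p = 1.6e-06). The adipogenic regulator Pparg had 3 counts after LPS against 982 in vehicle cells, a ratio of LPS to vehicle with a counting interval of 0.00229 to 0.0326 (adjusted p = 2.4e-06). Of the 1888 lower genes, 337 were at 0 in all 3 LPS libraries, the libraries with the excess of genes at 0 given above, and they included Birc5, Mcm7, Ccna2 and Plk1, 4 of the 32 measured cell cycle genes. In that list 2 of 32 rose and 11 fell (2 and 11 adjusted over the list alone). It did not pass as a group with all libraries (camera adjusted p = 0.054, and adjusted p = 0.37 with an estimated correlation). Without LPS replicate 3 it passed at the preset correlation (camera adjusted p = 0.026), and an estimated correlation was not run there. With only these 2 groups in the fit, 1250 genes were higher and 858 lower, so most calls were increases there.

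Compound against vehicle, without LPS, asked what dimethyl itaconate did to resting macrophages. The compound raised 137 and lowered 155 genes of 10285 (454 and 349 when LPS replicate 3, which is in neither group, was left out of the shared estimate of spread). Genes of oxidant defence rose: Slc7a11 was 12.8-fold higher (log2 3.68 ± 0.47, adjusted p = 0.00024). Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, was 11.8-fold higher (log2 3.57 ± 0.48, adjusted p = 0.00035). Among the decreases, the complement gene C1qa went from 456 ± 71.4 CPM to 55.8 ± 5.99 CPM, 8.17-fold lower (log2 -3.03 ± 0.30, adjusted p = 1.8e-05). The fractalkine receptor Cx3cr1 was 21.9-fold lower (log2 -4.45 ± 0.85, adjusted p = 0.0049).

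Of NRF2 targets 18 of 37 rose (25 adjusted over the list alone), the quinone reductase Nqo1 by 7.88-fold, the glutathione transferase Gsta3 by 9.12-fold and the reductase Ptgr1 by 5.73-fold (adjusted p = 0.0017, 9.8e-05 and 0.00021). The list rose as a group (camera adjusted p = 4.4e-28, and adjusted p = 0.0015 with an estimated correlation). Hmox1, the haem-degrading oxygenase, did not pass on its own (log2 0.98 ± 0.35, adjusted p = 0.19). For ATF4 stress response genes 3 of 33 rose (6 adjusted over the list alone), with the mitochondrial folate enzyme Mthfd2 3.13-fold higher (adjusted p = 0.015; camera adjusted p = 0.00070, and adjusted p = 0.031 with an estimated correlation). Genes of the unfolded protein response in the endoplasmic reticulum behaved alike: 2 of 21 rose (4 adjusted over the list alone), the chaperone Calr by 3.17-fold (camera adjusted p = 0.00034, and adjusted p = 0.031 with an estimated correlation). In the heat shock list 1 of 17 rose (5 adjusted over the list alone), Hsp90aa1 by 2.42-fold (camera adjusted p = 7.5e-06, and adjusted p = 0.15 with an estimated correlation). In the glycolysis list 1 of 29 rose (4 adjusted over the list alone), the glucose transporter Slc2a1 by 3.12-fold (camera adjusted p = 0.0043, and adjusted p = 0.33 with an estimated correlation). Without LPS replicate 3 these lists had 6, 5, 6 and 6 higher members in the same order.

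Among the 8 largest increases by rule were Serpinb9b, 36.2-fold higher (log2 5.18 ± 0.53, adjusted p = 2.1e-05), and its relative Serpinb9, a granzyme inhibitor, 13.1-fold higher (log2 3.71 ± 0.36, adjusted p = 1.8e-05). Slc16a9, a monocarboxylate transporter family member, was 33.5-fold higher (adjusted p = 7.0e-05), the growth factor receptor Met 24.9-fold higher (adjusted p = 0.0017). The protein C receptor Procr 14.2-fold higher (adjusted p = 2.1e-05). Acod1 itself was 7.26-fold higher (log2 2.86 ± 0.50, adjusted p = 0.0027), at 93.3 ± 41.6 against 13 ± 3.87 CPM. Nos2 had 23 counts in the compound libraries against 0, at least 6.20-fold higher, and did not pass (adjusted p = 0.17, and 0.035 without LPS replicate 3). Among the 8 largest decreases, besides C1qa and Cx3cr1, were Nptx1, 34.0-fold lower (log2 -5.09 ± 0.87, adjusted p = 0.0020), Clec4b1, 20.6-fold lower (adjusted p = 0.0038). Ms4a4c, 8.34-fold lower (adjusted p = 0.00075). Among macrophage markers 6 of 16 fell (8 adjusted over the list alone), including the immunoglobulin receptor Fcgr1 at 7.60-fold (adjusted p = 2.1e-05). The list fell as a group (camera adjusted p = 2.5e-11, and adjusted p = 0.0018 with an estimated correlation). In the antigen-presentation list 1 of 12 rose and 5 fell (1 and 7 adjusted over the list alone): H2-Aa, H2-Eb1 and H2-Ab1, which encode the chains that display peptides, fell 5.57-fold, 6.35-fold and 5.81-fold (adjusted p = 0.0014, 0.0015 and 0.0019). The list fell as a group (camera adjusted p = 9.4e-07, and adjusted p = 0.031 with an estimated correlation). Of type I interferon genes 3 of 36 rose and 9 fell (3 and 14 adjusted over the list alone). The interferon-induced Ifi44 fell 4.12-fold and the chemokine Cxcl10 rose 7.64-fold (adjusted p = 0.0014 and 0.0025). The list fell as a group at the preset correlation (camera adjusted p = 1.2e-05). That call was lost with an estimated correlation (adjusted p = 0.28). Among markers of neutrophils and their progenitors 1 of 11 rose and 2 fell (1 and 5 adjusted over the list alone), with the collagenase Mmp8 7.58-fold higher (adjusted p = 0.00021) and the gelatinase Mmp9 3.62-fold lower (adjusted p = 0.027; camera adjusted p = 0.011, and adjusted p = 0.31 with an estimated correlation). The summed level of macrophage markers, in unscaled CPM, was 15681.6 ± 2468 in vehicle cells and 8324 ± 1049 with the compound, and other lists fell as well: ribosomal protein genes from 34802 to 26180, stromal markers from 127.6 to 83.0, dendritic cell markers from 41.5 to 33.3, T and NK cell markers from 6.15 to 1.32. Neutrophil markers were at 665 ± 92.2 and 601.6 ± 122.

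**Figure D1:**
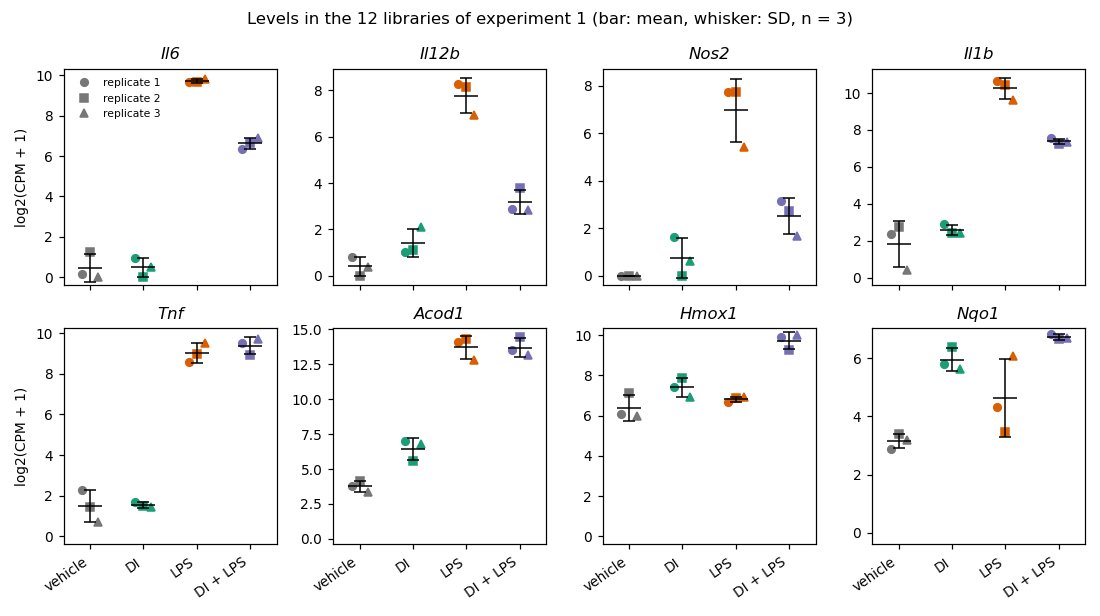
Each point is the level of a gene in 1 library, as log2 of TMM-scaled CPM plus 1, for 8 genes in the 12 libraries of experiment 1, with bars for the mean and whiskers for the SD of 3 libraries. Il6 had 845 ± 55.9 CPM after LPS and 98.9 ± 18.6 CPM after compound plus LPS, and Hmox1 had 112 ± 9.36 CPM and 867 ± 229 CPM, while Tnf and Acod1 did not pass the test between these groups.

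Compound plus LPS against LPS asked what prior dimethyl itaconate did to stimulated macrophages. With the compound 862 genes were higher and 774 lower of 10285 (985 and 963 without LPS replicate 3). Nos2 fell from 155 ± 98.4 CPM to 5.18 ± 2.85 CPM, 29.7-fold lower (log2 -4.89 ± 0.73, adjusted p = 0.00030). Il12b, a cytokine subunit that directs T cell responses, was 27.9-fold lower (log2 -4.80 ± 0.52, adjusted p = 1.1e-05). Il6 was 8.54-fold lower (log2 -3.09 ± 0.48, adjusted p = 0.00028), Il1b 7.66-fold lower (log2 -2.94 ± 0.49, adjusted p = 0.00056). The monocyte chemokine Ccl2 13.6-fold lower (log2 -3.77 ± 0.33, adjusted p = 1.9e-06). In the other direction the glutathione gene Gclc was 108-fold higher (log2 6.75 ± 0.57, adjusted p = 1.1e-06), Hmox1 7.75-fold higher (log2 2.96 ± 0.38, adjusted p = 5.1e-05). Cxcl2, a chemokine for neutrophils, 10.4-fold higher (log2 3.37 ± 0.38, adjusted p = 1.4e-05). Tnf (log2 0.36 ± 0.39, adjusted p = 0.58), Acod1 (log2 -0.06 ± 0.45, adjusted p = 0.95), Nlrp3 (log2 -0.22 ± 0.35, adjusted p = 0.72) and Atf3 (log2 0.30 ± 0.34, adjusted p = 0.60) did not pass, nor did Nfkbiz (log2 -0.59 ± 0.43, adjusted p = 0.39) or Hif1a (log2 -0.71 ± 0.42, adjusted p = 0.28). Without LPS replicate 3, Nfkbiz and Hif1a were called lower (log2 -1.0, adjusted p = 0.038, and log2 -1.15, adjusted p = 0.0062).

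Among inflammatory cytokines and chemokines 3 of 25 rose and 16 fell (4 and 16 adjusted over the list alone). The receptor antagonist Il1rn fell 8.36-fold, the anti-inflammatory cytokine Il10 27.4-fold and Il18 4.65-fold (adjusted p = 7.5e-06, 0.0037 and 0.0010). The list fell as a group at the preset correlation (camera adjusted p = 5.5e-08). That call was lost with an estimated correlation (adjusted p = 0.085). In the list of genes that depend on Nfkbiz, 9 of 13 fell (9, and 1 higher, adjusted over the list alone). Its lower members Ccl2, Il12b and Il6, among others, were also counted with the lower cytokines. The group call held with an estimated correlation (camera adjusted p = 4.9e-11, and adjusted p = 0.0012 with an estimated correlation). Its lowest member was the vasoconstrictor gene Edn1, 97.4-fold lower (log2 -6.61 ± 0.72, adjusted p = 1.1e-05). Of NF-kB feedback genes 1 of 28 rose and 10 fell (3 and 11 adjusted over the list alone), with the phosphatase Dusp2 at 16.1-fold, Socs3 at 6.48-fold and the NF-kB subunit Rel at 2.61-fold lower (adjusted p = 1.6e-05, 8.5e-05 and 0.0023). The list had camera adjusted p = 5.0e-06, and adjusted p = 0.052 with an estimated correlation. With a replicate block and an estimated correlation, camera gave adjusted p = 0.047. Interferon gamma response genes fell together: 17 of 27 fell (21 adjusted over the list alone), with the chemokine Cxcl9 at 16.4-fold, the guanylate-binding protein Gbp4 at 19.1-fold and the transcription factor Irf8 at 12.0-fold (adjusted p = 1.1e-05, 1.3e-05 and 4.3e-05; camera adjusted p = 2.3e-16, and adjusted p = 0.0016 with an estimated correlation). Of type I interferon genes 7 of 36 fell (8 adjusted over the list alone), among them Ifnb1, which encodes interferon beta, at 8.90-fold lower (log2 -3.15 ± 0.76, adjusted p = 0.012). The group call (camera adjusted p = 1.4e-06) was lost (adjusted p = 0.19 with an estimated correlation), and 19 members were lower without LPS replicate 3. Of inflammasome and pyroptosis genes 3 of 18 rose and 8 fell (3 and 9 adjusted over the list alone). The adaptor Pycard fell 6.39-fold and Il1a 12.4-fold (adjusted p = 1.4e-05 and 0.00064). The list had camera adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation. Its lower members Il1a, Il1b and Il18 were also counted with the cytokines, and Gbp5 with the interferon gamma genes. In the antigen-presentation list 7 of 12 fell (7, and 1 higher, adjusted over the list alone), the costimulatory ligand Cd86 by 5.6-fold and the class II chain H2-Eb1 by 5.64-fold (adjusted p = 0.00033 and 0.0012; camera adjusted p = 1.5e-05, and adjusted p = 0.085 with an estimated correlation). Among macrophage markers 6 of 16 fell (6 adjusted over the list alone), with Fcgr1 8.27-fold and C1qa 4.36-fold lower (adjusted p = 4.9e-06 and 9.4e-05). The list had camera adjusted p = 0.0078, and adjusted p = 0.061 with an estimated correlation. Its summed level, in unscaled CPM, did not fall: it was 5936 ± 1199 with LPS and 6288 ± 459 with compound plus LPS.

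NRF2 targets rose together under LPS with the compound: 26 of 37 rose (30 adjusted over the list alone). The call held with an estimated correlation (camera adjusted p = 2.0e-24, and adjusted p = 0.00039 with an estimated correlation). Gsta3 was 33.6-fold higher (log2 5.07 ± 0.48, adjusted p = 3.6e-06), Ptgr1 10.4-fold higher (log2 3.38 ± 0.34, adjusted p = 5.1e-06). The sulfiredoxin Srxn1, which repairs peroxiredoxins, 6.87-fold higher (log2 2.78 ± 0.29, adjusted p = 7.8e-06). Nqo1 was 3.74-fold higher (log2 1.90 ± 0.49, adjusted p = 0.014) and had log2 2.80, adjusted p = 1.6e-05 without LPS replicate 3. For ATF4 stress response genes 9 of 33 rose and 2 fell (16 and 3 adjusted over the list alone), with Slc7a11 7.85-fold higher (log2 2.97 ± 0.44, adjusted p = 0.00020) and the translation repressor Eif4ebp1 6.05-fold higher (adjusted p = 0.00040), and with Nupr1 4.38-fold lower (adjusted p = 0.00048; camera adjusted p = 0.0020, and adjusted p = 0.031 with an estimated correlation). Of these 33 genes, 7 were at 0 in all libraries of a group. In the glycolysis list 8 of 29 rose and 2 fell (10 and 3 adjusted over the list alone): the enzymes Pkm and Pgam1 were 2.62-fold and 2.79-fold higher (adjusted p = 0.0032 and 0.0017), while Hk2 and Pfkfb3, which admit glucose to the pathway and drive its flux, were 3.96-fold and 4.14-fold lower (adjusted p = 0.0023 and 0.0015). Its group call (camera adjusted p = 0.017, and adjusted p = 0.40 with an estimated correlation) was also lost without LPS replicate 3 (camera adjusted p = 0.080). In the TCA cycle list 3 of 27 rose (0 adjusted over the list alone), Idh1, Slc25a1 and Slc25a11, with Sdha among those that did not pass (log2 0.20 ± 0.36, adjusted p = 0.75). With a replicate block only Idh1 was called, and without LPS replicate 3 only Slc25a1 and Aco1. Among cholesterol synthesis genes 2 of 19 fell (2 adjusted over the list alone), among them Insig1, at 5.51-fold with all libraries and at log2 -1.0, adjusted p = 0.015 without LPS replicate 3. The list's median and mean were positive (0.24 and 0.31) and its test pointed down (camera adjusted p = 0.51). Of the housekeeping genes 3 of 13 rose and 1 fell (3 and 1 adjusted over the list alone): Actb, which was used to balance the library pools, was 3.69-fold lower (adjusted p = 0.00045). Pgk1 3.01-fold higher (adjusted p = 0.0035).

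Of the 862 genes higher with compound plus LPS, 112 were at 0 in every LPS library, the libraries with the excess of genes at 0, so the order of their increases is not known. Acer2, an alkaline ceramidase, was at least 44.6-fold higher (adjusted p = 0.00016), Tmc8 at least 40.6-fold higher (adjusted p = 1.9e-05), Angptl2 at least 25.6-fold higher (adjusted p = 0.00057), and the alcohol dehydrogenase Adh7 at least 24.3-fold higher (adjusted p = 0.0031). The gamma-secretase gene Aph1b and Dennd2a were at least 22.9-fold and 16.6-fold higher (adjusted p = 0.00079 and 0.00060). Tacc2 had 745 counts against 1, a ratio with a counting interval of 61.6 to 13607. Of the 774 lower genes 9 were at 0 in every compound plus LPS library. Among them, the endothelial adhesion receptor Sele was at least 55.6-fold lower (adjusted p = 0.00097) and the transcriptional repressor Gfi1 at least 24.5-fold lower (adjusted p = 0.0039). The endothelial lipase Lipg fell from 432 ± 222 CPM to 4.96 ± 2.76 CPM, 89.4-fold lower (log2 -6.48 ± 0.71, adjusted p = 1.2e-05). With only these 2 groups in the fit, 273 genes were higher and 380 lower.

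Compound plus LPS against compound asked how compound-treated cells answered LPS, in libraries that the LPS against vehicle comparison did not use. LPS raised 1170 and lowered 778 genes in compound-treated cells (1556 and 1275 without LPS replicate 3 in the shared fit). Tnf rose 355-fold (log2 8.47 ± 0.56, adjusted p = 1.1e-08), Acod1 153-fold (log2 7.26 ± 0.60, adjusted p = 7.3e-08), and Cxcl2 977-fold (log2 9.93 ± 0.51, adjusted p = 1.6e-09). Smaller increases were measured for Nos2, 5.59-fold higher (log2 2.48 ± 0.80, adjusted p = 0.038), and Il12b, 4.46-fold higher (log2 2.16 ± 0.53, adjusted p = 0.0068). Il18 did not pass (log2 0.92 ± 0.39, adjusted p = 0.11). Of inflammatory cytokines 22 of 25 rose (23 adjusted over the list alone), of NF-kB feedback genes 25 of 28 rose (26, and 1 lower, adjusted over the list alone). Of the Nfkbiz list 12 of 13 rose (12 adjusted over the list alone). Of type I interferon genes 36 of 36 rose (36 adjusted over the list alone). Of interferon gamma genes 25 of 27 rose (25 adjusted over the list alone). Each held as a group with an estimated correlation (adjusted p = 0.00062, 0.00019, 0.00019, 0.00019 and 0.00018). Of NRF2 targets 10 of 37 rose (17 adjusted over the list alone), the autophagy receptor Sqstm1 by 7.16-fold and Hmox1 by 4.98-fold (adjusted p = 7.1e-06 and 0.00014; camera adjusted p = 0.00060, and adjusted p = 0.14 with an estimated correlation), and 20 rose without LPS replicate 3. In the glycolysis list 11 of 29 rose and 1 fell (15 and 2 adjusted over the list alone), the phosphofructokinase Pfkp by 4.69-fold (adjusted p = 7.2e-05; camera adjusted p = 0.00023, and adjusted p = 0.29 with an estimated correlation). In the inflammasome list 9 of 18 rose (10, and 1 lower, adjusted over the list alone), with camera adjusted p = 1.5e-07, and adjusted p = 0.034 with an estimated correlation. Scaling by DESeq2 size factors moved the median of all genes by -0.14 on the log2 scale in this comparison and gave 1030 higher and 1014 lower genes, so its small decreases and increases are relative to that shift.

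The interaction asked whether the effect of the compound differed with and without LPS, or equally whether the LPS response differed with the compound. It was called for 143 genes with a more positive and 156 with a more negative compound effect under LPS (346 and 460 without LPS replicate 3). Il12b did not pass without LPS (log2 1.90 ± 0.71, adjusted p = 0.19) and fell 27.9-fold with it, a difference of log2 -6.71 ± 0.84 (adjusted p = 0.00023). Cxcl9 rose 4.62-fold with the compound in resting cells and fell 16.4-fold in stimulated cells (log2 -6.24 ± 0.63, adjusted p = 3.7e-05), and Gbp4, Socs1 and Irf8 also had more negative effects under LPS (log2 -6.02 ± 0.75, -4.56 and -3.84; adjusted p = 0.00023, 0.00041 and 0.0013). Il1b (log2 -3.60 ± 0.72, adjusted p = 0.011), Il18 (log2 -2.11 ± 0.55, adjusted p = 0.046) and Acod1 (log2 -2.92 ± 0.67, adjusted p = 0.023) passed in the same direction, as did Lipg (log2 -7.88 ± 1.11, adjusted p = 0.00046). Hmox1 (log2 1.98 ± 0.51, adjusted p = 0.041) and Cxcl2 (log2 3.42 ± 0.51, adjusted p = 0.00077) had the opposite sign. Il6 did not pass (log2 -3.84 ± 1.08, adjusted p = 0.058), nor did Tnf, Nqo1 or Nlrp3 (adjusted p = 0.69, 0.43 and 0.83). Without LPS replicate 3 Il6 passed (log2 -3.89, adjusted p = 0.022). Of interferon gamma response genes 10 of 27 had a more negative effect (11 adjusted over the list alone; camera adjusted p = 3.1e-14, and adjusted p = 0.0084 with an estimated correlation). Of the Nfkbiz list 3 of 13 did (4 adjusted over the list alone; camera adjusted p = 1.2e-06, and adjusted p = 0.0084 with an estimated correlation). For inflammatory cytokines 3 of 25 were more positive and 10 more negative (4 and 12 adjusted over the list alone; camera adjusted p = 9.6e-08, and adjusted p = 0.16 with an estimated correlation). For NRF2 targets 5 of 37 were more positive (9 adjusted over the list alone; camera adjusted p = 0.0035, and adjusted p = 0.16 with an estimated correlation). The 6 genes with the largest positive fitted differences by rule, Tmc8, Crat, Ipo4, Mad2l1bp, Aph1b and Napb, were at 0 in all 3 LPS libraries and at 23, 6.82, 7.51, 6.71, 13.2 and 7.41 CPM with compound plus LPS.

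Genes that LPS induced were often lower with the compound. Of the 1641 LPS-induced genes, 563 (34.3%) were lower and 61 higher in compound plus LPS than in LPS, against 123 and 138 for independent lists. Of the 1888 LPS-repressed genes, 486 (25.7%) were higher and 23 lower, against 158 and 142. These comparisons share the LPS libraries, so noise in them alone pushes the fold changes in opposite directions. In 40 simulations with shared libraries and no compound effect, almost no gene was called for the compound and at most 1 lay in either overlap, so the covariance of the 2 fold changes over all tested genes was set beside its simulated value: -2.56 in the data against a mean of -0.274 and a lowest value of -0.340 (correlation -0.71 against -0.19 and -0.23). Genes at 0 in a group carried much of it: over the 9854 genes with counts in all 4 groups the covariance was -1.19 (simulated mean -0.180, lowest -0.208) and the correlation -0.57 (-0.171 and -0.197). The induced genes had a median LPS response of 2.09 on the log2 scale in vehicle cells and 1.27 in compound-treated cells, against 1.97 and 1.96 in the simulations, and the repressed genes -2.41 (-2.20 with genes at 0 at their bound) and -0.98, against -2.24 and -1.85. The simulations called a mean of 1993 induced and 2300 repressed genes, more than the data. Over genes, LPS libraries deviated from the others of their group with an SD of 0.949, 0.963 and 1.63 on the log2 scale. Elsewhere in experiment 1 this SD was 0.356 to 0.578. The simulated values may therefore understate what noise in the shared LPS libraries gives. Without LPS replicate 3 the overlaps were 688 lower and 87 higher of 1942, and 556 higher and 35 lower of 2084.

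Irg1 knockout against wild type asked what loss of the itaconate-making enzyme did under LPS and interferon gamma. Acod1 was lower in every knockout library, at 24.9 ± 8.86 against 4352 ± 285 CPM, 173-fold lower (log2 -7.43 ± 0.32, adjusted p = 4.8e-07). Few other genes passed among 9491 tested: 1 was higher and 5, Acod1 included, were lower (with a term for replicate number, 275 and 319). Mt2, a metal-binding metallothionein, was 4.07-fold lower (log2 -2.02 ± 0.24, adjusted p = 0.0080), and Erdr1 4.37-fold lower (log2 -2.13 ± 0.18, adjusted p = 0.00044). Tgfbi, an extracellular matrix protein, was 2.76-fold higher (log2 1.47 ± 0.21, adjusted p = 0.030). A further lower transcript, G530011O06Rik, was chosen after its values were seen (log2 -2.51 ± 0.27, adjusted p = 0.0032). With the replicate term Acod1, Mt2, Erdr1 and Tgfbi had log2 values of -7.43, -2.04, -2.13 and 1.47. In their deviations from the group mean, libraries with the same number resembled each other across genotypes, with correlations of 0.544 to 0.665 across genes. Other pairs had -0.375 to -0.222, which is no separate evidence. The deviations within a group cancel out, so positive values for the same number push the others below it. Because of this resemblance both fits are given.

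Inflammatory genes moved in both directions with the replicate term, and each call in this paragraph comes from that fit. Il12b was 1.96-fold lower (log2 -0.97 ± 0.10, adjusted p = 2.6e-09), Il1b 1.47-fold higher (log2 0.56 ± 0.13, adjusted p = 0.0035), and Nlrp3 1.45-fold higher (log2 0.53 ± 0.12, adjusted p = 0.0039). Without the term they had adjusted p = 0.26, 0.67 and 0.68. Saa3, an acute phase protein, was 1.86-fold higher (log2 0.90 ± 0.09, adjusted p = 2.2e-09), the GTPase Irgm1 2.12-fold higher (log2 1.08 ± 0.10, adjusted p = 4.7e-10), and Cd86 1.41-fold lower (log2 -0.49 ± 0.11, adjusted p = 0.0020), with adjusted p = 0.13, 0.059 and 0.67 without the term. Among inflammatory cytokines 1 of 20 rose and 6 fell (1 and 9 adjusted over the list alone). In the inflammasome list 6 of 18 rose (6, and 1 lower, adjusted over the list alone), with camera adjusted p = 2.8e-05 and 0.11 (for the cytokines adjusted p = 0.21 with an estimated correlation). Without the term 0 of 20 passed with edgeR (0 higher and 2 lower adjusted over the list alone, 1 higher and 6 lower at an unadjusted p under 0.05, DESeq2 0 and 1, voom 0 and 0) for the cytokines. In the interferon gamma list 4 of 29 rose and 3 fell (5 and 6 adjusted over the list alone). In the type I list 1 of 36 rose and 6 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 0.93 and 0.022 (for type I adjusted p = 0.34 with an estimated correlation). Nos2 (log2 0.29 ± 0.09, adjusted p = 0.058), Il6 (log2 0.22 ± 0.20, adjusted p = 0.63), Tnf (log2 0.28 ± 0.13, adjusted p = 0.23), Hmox1 (log2 0.30 ± 0.11, adjusted p = 0.10) and Sdha (log2 -0.05 ± 0.14, adjusted p = 0.90) did not pass in either fit, and Il10 was below the count filter.

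As a group NRF2 targets were lower in the knockout at the preset correlation (camera adjusted p = 2.0e-09). With an estimated correlation the list did not pass (adjusted p = 0.082). The sign was opposite to its change with the compound. Without the replicate term 0 of 36 passed with edgeR (0 higher and 4 lower adjusted over the list alone, 0 higher and 12 lower at an unadjusted p under 0.05, DESeq2 0 and 1, voom 0 and 0), while with it 17 of 36 fell (23, and 1 higher, adjusted over the list alone), with camera adjusted p = 6.8e-15, and adjusted p = 0.21 with an estimated correlation. Slc7a11 was 2.43-fold lower (log2 -1.28 ± 0.16, adjusted p = 2.1e-07), Ptgr1 1.90-fold lower (log2 -0.93 ± 0.12, adjusted p = 2.6e-07), Gclc 1.78-fold lower (log2 -0.83 ± 0.12, adjusted p = 1.9e-06), Srxn1 1.72-fold lower (log2 -0.78 ± 0.12, adjusted p = 7.4e-06) and Nqo1 1.98-fold lower (log2 -0.98 ± 0.28, adjusted p = 0.024) with the term. Without it they had adjusted p = 0.39, 0.57, 0.28, 0.26 and 0.54. Glycolysis and HIF-1 target genes had the same direction: 12 of 28 fell (15 adjusted over the list alone) with the term (camera adjusted p = 7.2e-10, and adjusted p = 0.21 with an estimated correlation), among them Slc2a1 at 1.56-fold lower (adjusted p = 4.1e-05) and the mitophagy receptor Bnip3 at 1.52-fold lower (adjusted p = 5.8e-05). Without the term 0 of 28 passed with edgeR (0 higher and 1 lower adjusted over the list alone, 0 higher and 7 lower at an unadjusted p under 0.05, DESeq2 0 and 0, voom 0 and 0). In the heat shock list 3 of 17 fell (5 adjusted over the list alone) with the term, Hspa1b by 2.37-fold (adjusted p = 2.5e-08; camera adjusted p = 7.8e-05, and adjusted p = 0.21 with an estimated correlation). In the list of alternative activation markers 5 of 9 fell with the term (6 adjusted over the list alone), among them the folate receptor Folr2 at 1.6-fold (adjusted p = 0.00093). The list's camera test gave adjusted p = 7.5e-05, and adjusted p = 0.21 with an estimated correlation. Without the term 0 were higher and 4 lower at an unadjusted p under 0.05 (DESeq2 0 and 0, voom 0 and 0). Of respiratory chain genes 3 of 52 fell with the term (5 adjusted over the list alone), with camera adjusted p = 0.00020, and adjusted p = 0.64 with an estimated correlation. Without the term 1 was lower at an unadjusted p under 0.05 (DESeq2 0 and 0, voom 0 and 0). Of lysosome genes 5 of 29 fell with the term (6, and 1 higher, adjusted over the list alone), with Gpnmb 1.71-fold lower (adjusted p = 4.1e-08). The lysosome list had camera adjusted p = 0.00029, and adjusted p = 0.25 with an estimated correlation. Without the term 3 of its members were lower at an unadjusted p under 0.05 (DESeq2 0 and 1, voom 0 and 0). The itaconate and anaplerosis list holds Acod1 itself, the knocked-out gene, so its group test cannot show whether the other members moved. With the replicate term it gave camera adjusted p = 7.2e-10, and adjusted p = 0.21 with an estimated correlation. In that fit 1 of 13 rose and 2 fell (1 and 4 adjusted over the list alone), with the methylmalonyl-CoA mutase gene Mmut 1.82-fold higher (adjusted p = 0.0013).

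**Figure D2:**
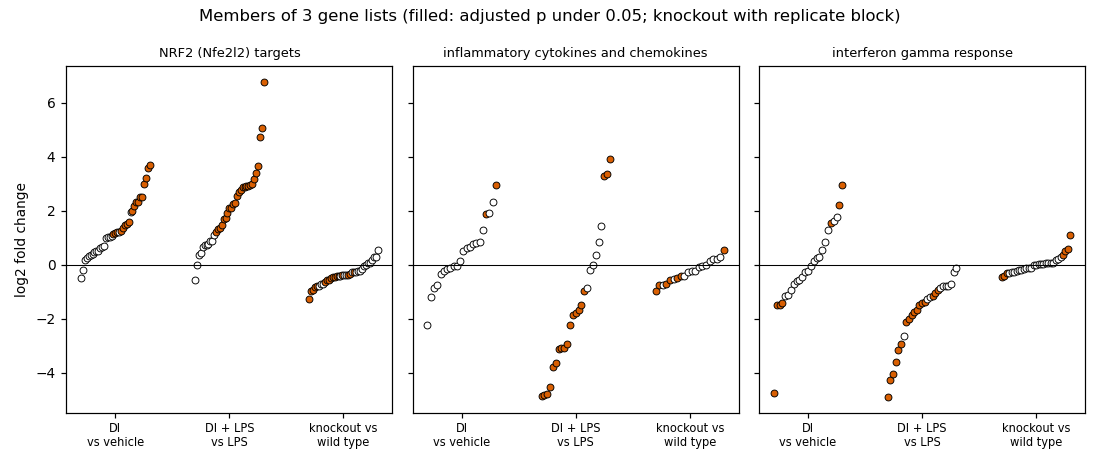
Each point is the fitted log2 fold change of 1 member of a list fixed before the data were examined, in 3 comparisons, with filled points for adjusted p under 0.05 and the knockout fitted with a term for replicate number. Of the NRF2 targets 18 rose with the compound alone and 26 with compound plus LPS, and 17 fell in the knockout.

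Genes that the compound moved were then examined in the knockout, where no library is shared. The 132 tested genes that were higher with the compound alone had a median of -0.24 on the log2 scale in knockout against wild type (camera p = 6.5e-13, and p = 0.0052 with an estimated correlation), and 41 of them were called lower with the replicate term, against 4.40 for independent lists, and 5 higher, against 3.91. Without LPS replicate 3 the set grew to 439 genes and its median with the replicate term shrank to -0.041 (camera p = 7.8e-05, and p = 0.018 with an estimated correlation). Without the term 1 of the 132, Acod1 itself, was called lower and 0 higher. Acod1 is the knocked-out gene, so its own fall is no evidence, and the set was not tested without it. Those lower with it included Acod1, Gclc, Nqo1, Ptgr1 and Procr. The 139 genes lower with the compound alone had a median of 0.10 (camera p = 0.0021, and p = 0.19 with an estimated correlation), and with the term 29 were called higher, against 4.12, and 7 lower, against 4.63 (0 and 0 without it). Aif1, C1qa and Irgm1 were among those higher. For the 791 genes higher with compound plus LPS the median was -0.06 (camera p = 0.0074, and p = 0.0015 with an estimated correlation), with 70 called lower with the term, against 26.4, and 11 higher, against 23.5 (0 and 0 without it). The 709 genes lower there did not move as a group (camera p = 0.48, and p = 0.22 with an estimated correlation). Of them 61 were called higher with the term, against 21.0, and 42 lower, against 23.6 (0 higher and 2 lower without it). Across 9242 genes, which are not independent replicates, Spearman correlations of the fold changes were -0.037 for the compound alone and -0.070 with LPS.

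**Figure D3:**
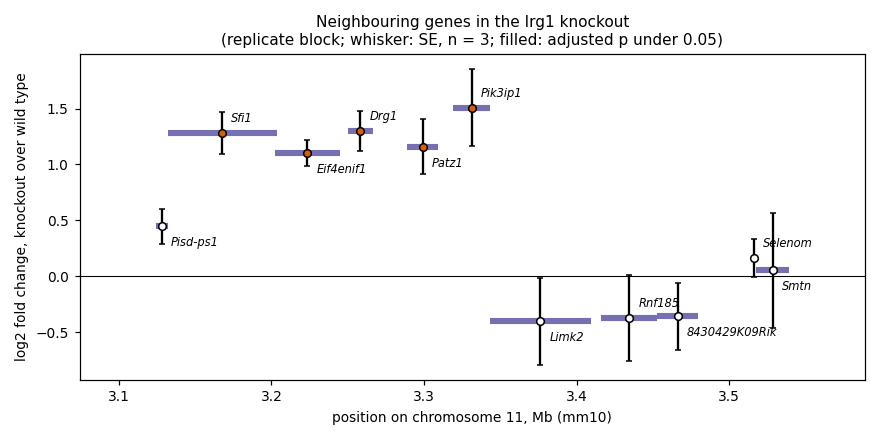
Points are log2 fold changes in knockout against wild type with the replicate term, with the standard error as whiskers and horizontal bars for the gene bodies, by position on chromosome 11 (mm10). The 5 adjacent genes from Sfi1 to Pik3ip1 were called higher, with log2 values from 1.10 to 1.51.

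Neighbouring genes moved together in the knockout. On chromosome 11, from 3131850 to 3342971, 5 adjacent tested genes were higher with the replicate term: Sfi1 (log2 1.28 ± 0.19), Eif4enif1 (log2 1.10 ± 0.12), Drg1 (log2 1.30 ± 0.18), Patz1 (log2 1.16 ± 0.24) and Pik3ip1 (log2 1.51 ± 0.35), with adjusted p of 5.1e-06, 4.1e-09, 1.7e-06, 0.0013 and 0.0035. Without the term none passed (adjusted p = 0.11, 0.053, 0.15, 0.41 and 0.24). Sfi1 ends at 3203347 and Eif4enif1 starts at 3202343, so these genes overlap. As the strand option of the counting is not given, they may share reads. Pik3ip1 was named by rule, and the other 4 were chosen after their values were seen.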

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

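The results in this part were singled out because the effect of the compound differed between cells with and without LPS by a test of the interaction; for the 2 patterns weighed here, the tests of depth, of replicate 3 and of other splits were chosen after the result was seen. The compound effect was more positive under LPS for 143 genes and more negative for 156. In the panel, Il12b (log2 -6.71 ± 0.84, adjusted p = 0.00023), Nos2 (adjusted p = 0.0042), Il1b (log2 -3.60 ± 0.72, adjusted p = 0.011), Acod1 (log2 -2.92 ± 0.67, adjusted p = 0.023) and Il18 (log2 -2.11 ± 0.55, adjusted p = 0.046) had a more negative effect, and Hmox1 (log2 1.98 ± 0.51, adjusted p = 0.041) a more positive effect. Nos2 was at 0 in all vehicle libraries, so only a lower bound on the size of its difference could be set. Among the largest negative differences were Lipg (log2 -7.88 ± 1.11, adjusted p = 0.00046), Shisa3 (adjusted p = 0.0059), and Sele, Gfi1 and Mab21l3 (adjusted p = 0.016, 0.018 and 0.028), the last 3 at 0 in all compound plus LPS libraries. The 6 largest positive fitted differences were Tmc8 (adjusted p = 0.00083), Crat (adjusted p = 0.0040), Mad2l1bp (adjusted p = 0.0052), Napb (adjusted p = 0.013), Ipo4 (adjusted p = 0.020) and Aph1b (adjusted p = 0.024), all at 0 in the 3 LPS libraries.

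Of 50 splits of the libraries within the arms with and without LPS, 4 gave 299 interaction genes or more, the real split, which had 299, included, and the highest other split had 458. The other 3 keep the real division of the libraries that received LPS and with it the compound effect there, so they do not show what chance alone gives, and this test leaves open whether chance can be excluded for the count. Splits that break that division gave at most 2 genes.

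The first pattern is the excess of genes at 0 in the LPS libraries. It counts genes at 0 in a single library that the other libraries of its group predict. Genes at 0 in all LPS libraries, among them those with the 6 largest positive fitted differences, are not counted in it. Repression alike in all LPS libraries would not add to it. After thinning all libraries to 955718 counts, 0.202%, 0.459% and 6.37% of predicted genes were at 0 in LPS replicates 1, 2 and 3. In the other 9 libraries of experiment 1 at most 0.0694% were, which argues against lower depth. At equal depth the excess was by far largest in replicate 3, which also helped to predict genes for replicates 1 and 2. With replicate 2 alone predicting replicate 1 the share was 0.400%, and 0.858% in the reverse case. Such single predictions in the other groups gave at most 0.158%. Among genes not called in LPS against vehicle the thinned LPS values were 0.264%, 0.617% and 8.21%, against at most 0.0828%. Transcripts lost at random in library making thus remain a candidate explanation, in a test chosen before its result was seen. Repression by LPS was also tested by a prediction made before its result, on another set. It held 89 genes at 0 in all LPS libraries and at 5 CPM or more in vehicle cells. For them repression cannot be told apart from such loss. In compound plus LPS against compound 35 were lower (39.3%, against 8.66% of 8127 tested genes), 1 was higher and 53 were not called. Fold changes of genes at 0 in LPS libraries may mix both, and the share of each stays open.

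The second pattern is LPS replicate 3, whose log2 CPM correlated with replicates 1 and 2 at 0.70 and 0.735 over 856 abundant genes, while those 2 correlated at 0.928. Low depth is argued against, since replicates 1 and 2 thinned to its total still correlated at 0.926. GC content (Spearman rho 0.113) and transcript length (rho -0.09) were weak correlates of its deviation, which argues against both. Mixed-in RNA of the compound plus LPS group is also argued against: over the 594 genes higher in compound plus LPS the median lay -0.080 of the way to that group, over the 804 lower genes 0.448, and Prdx1 lay 3.0 times the whole way. Genes lost in replicate 3 could lower the first median as well. RNA of cells given the compound without LPS was not tested. Loss of transcripts in library making was tested only for the first pattern, where replicate 3 had the largest share at 0 (6.37% after thinning). It remains a candidate here, but its part in the low correlations was not tested. No other explanation was tested, and no biological explanation was tested, since the labels give none for a single replicate.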

How the results depend on the processing

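In this part the splits of samples, the fits without LPS replicate 3 for comparisons that do not hold it, and the block in experiment 2 alone were chosen after the results were seen. No call of a named gene or list turned direction under an alternative run, but the balance of higher and lower counts turned in places. Lower genes outnumbered higher ones in compound plus LPS against LPS with DESeq2-type size factors (777 and 842) and DESeq2 (1025 and 1109), and in compound plus LPS against compound with DESeq2 (1205 and 1306). Higher genes outnumbered lower ones in compound against vehicle without a filter (236 and 222) and without LPS replicate 3 (454 and 349). They also did for the interaction without LPS replicate 1 (343 and 199) or 2 (184 and 163). With only the 2 groups in the fit, compound plus LPS against LPS gave 273 higher and 380 lower genes, LPS against vehicle 1250 higher and 858 lower, compound against vehicle 557 higher and 456 lower, and compound plus LPS against compound 1539 lower. Calls fell in the comparisons that hold the LPS group and rose in those without it. DESeq2 gave 297 higher and 326 lower genes for compound against vehicle, 1306 lower for compound plus LPS against compound, 380 and 382 for the interaction, and 15 and 29 for the knockout. Limma-voom gave 250 and 255 for compound against vehicle. Without a count filter, compound against vehicle had 236 higher, the interaction 236 and 261, and the knockout 15 and 25. With robust spread the knockout had 2 higher and 8 lower, and with a replicate block 275 and 319. Genes lower with the compound alone lost their group call in the knockout with an estimated correlation (p = 0.185). The cause of these changes was not tested.

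Leaving out single libraries also moved counts. Higher genes in compound plus LPS against LPS ranged from 499 (without compound plus LPS replicate 1; 563 without replicate 2) to 1106 (without LPS replicate 1), and lower genes from 386 (without compound plus LPS replicate 1; 440 without replicate 2 and 496 without replicate 3) to 963 (without LPS replicate 3). Compound against vehicle ranged from 61 (without vehicle replicate 1) to 454 (without LPS replicate 3) higher and from 75 (without compound replicate 2) to 349 (without LPS replicate 3) lower; leaving out any library of either group lowered both counts, since fewer libraries remain, and leaving out LPS replicate 3 raised them. Compound plus LPS against compound ranged from 451 (without compound plus LPS replicate 3) to 1275 (without LPS replicate 3) lower. The interaction ranged from 52 (without compound replicate 1) to 346 (without LPS replicate 3; 343 without LPS replicate 1) higher and from 78 (without vehicle replicate 1) to 460 (without LPS replicate 3) lower. The knockout ranged from 0 to 1 higher and from 3 (without replicate 3 of either genotype) to 5 lower; edgeR gave 0 higher on leaving out any library except knockout replicate 2, with 495 to 741 genes of either direction at an unadjusted p under 0.05. LPS-repressed genes lower with the compound numbered 35 without LPS replicate 3, against 23.

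Of the named genes, leave-one-out fits kept side and direction for 3098 gene settings, lost the call for 401 and gained it for 10. DESeq2 kept 475 of them, with 3 lost and 14 gained, limma-voom 489 with 14 lost, no filter 475 with 11 lost and 17 gained, DESeq2-type size factors 497 with 6 lost, robust spread 499 with 2 lost and 2 gained, a stricter filter 468 with 1 lost, a replicate block 412 with 14 lost and 77 gained, and 2 groups alone 309 with 33 lost and 2 gained. For lists, estimated correlation kept 140 and lost 28, size factors kept 168, a block kept 167 and gained 1, and leave-one-out kept 1202, lost 11 and gained 19. The floor was highest in LPS replicate 3, where 3 counts correspond to 3.14 CPM. The 10 splits of 3 against 3 libraries are too few for a share under 0.05: real counts were 1636, 3529, 292, 1948 and 6 for compound plus LPS against LPS, LPS against vehicle, compound against vehicle, compound plus LPS against compound and knockout against wild type, only 1 split (the real one) gave as many, and the highest other split had 0 in each; swapping pairs in the blocked knockout fit gave 0 against 594 in each of 3 other arrangements, which are also too few for a share under 0.05.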

Other observations

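The tests of neighbouring genes in this part were chosen after the result was seen, as were the list tests without LPS replicate 3 and the genes named from short lists of markers. Several metabolic lists hardly moved with the compound alone: of TCA cycle genes 0 of 27 passed with edgeR (1 higher and 0 lower adjusted over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05, DESeq2 1 and 0, voom 1 and 0), and of respiratory chain genes 0 of 52 passed with edgeR (0 higher and 0 lower adjusted over the list alone, 2 higher and 0 lower at an unadjusted p under 0.05, DESeq2 0 and 0, voom 0 and 0). In LPS-treated cells with the compound, 1 of 52 fell (0 adjusted over the list alone) in the respiratory chain list (Ndufs4), and 2 of 29 rose (2 adjusted over the list alone) in the lysosome list (Atp6v1h and Lipa). With LPS alone, 3 of 19 rose and 4 fell (3 and 5 adjusted over the list alone) in the cholesterol synthesis list, 4 of 21 rose and 1 fell (4 and 0 adjusted over the list alone) in the unfolded protein list, and 2 of 52 rose (2 adjusted over the list alone) in the respiratory chain list (Cycs and Ndufs4). For ATF4 genes 8 of 33 rose and 11 fell (8 and 11 adjusted over the list alone) with LPS, where the median (-0.64) and mean (-1.07) were negative and the test pointed up (camera adjusted p = 0.89). The LPS medians and means of MHC class II genes (-0.29 and 0.87), itaconate genes (-0.41 and 0.70) and housekeeping genes (-0.32 and 0.12) differed in sign, as did those of LXR genes with compound plus LPS (-0.20 and 0.09). For ribosomal protein genes 0 of 48 passed with edgeR (0 higher and 0 lower adjusted over the list alone, 0 higher and 4 lower at an unadjusted p under 0.05, DESeq2 0 and 0, voom 0 and 0) with the compound alone, and the list's group call (camera adjusted p = 0.048) was lost (adjusted p = 0.52 with an estimated correlation). Of heat shock genes 8 of 17 rose (8 adjusted over the list alone) with LPS, a group call absent with all libraries (camera adjusted p = 0.094, and adjusted p = 0.59 with an estimated correlation) and present without LPS replicate 3 at the preset correlation (camera adjusted p = 0.018), where an estimated correlation was not run. Of alternative activation markers 6 of 13 rose and 1 fell (6 and 2 adjusted over the list alone) with LPS and 1 of 13 rose and 4 fell (2 and 5 adjusted over the list alone) with compound plus LPS against LPS.

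Markers of other cell types were lower than those of macrophages, in unscaled CPM summed over each list. Neutrophil and progenitor markers had group means of 112 to 665 CPM (145 ± 10.2 in the knockout against 112 ± 5.07 in wild type), B cell markers 1.68 to 8.78, T and NK cell markers 1.32 to 11.7, erythroid markers 0.490 to 8.99, dendritic cell markers 29.0 to 47.5, mast cell markers 1.40 to 30.3, stromal markers 25.8 to 127.6 and osteoclast markers 169 to 637.6, against 5936 to 15681.6 for macrophage markers. With compound plus LPS, against LPS, T and NK cell markers went from 11.7 to 1.72 CPM, mast cell markers from 30.3 to 5.16 and neutrophil markers from 333 to 462. There Lck, Hdc, Fscn1, Col3a1, Acp5 and Nfatc1 were called lower and Mmp8 and S100a8 higher, beside the changes of immune lists in that comparison. With LPS, 1 of 1 measured mast cell markers, Hdc, rose 110.4-fold (adjusted p = 1.5e-06), a gene that the Nfkbiz list also holds. In the same comparison 1 of 2 rose (1 adjusted over the list alone) in the T and NK cell list (Lck), 1 of 5 rose (1 adjusted over the list alone) in the dendritic cell list (Fscn1), and 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone) in the osteoclast list (Acp5 and Atp6v0d2). For stromal cells 0 of 9 passed with edgeR (0 higher and 0 lower adjusted over the list alone, 1 higher and 0 lower at an unadjusted p under 0.05, DESeq2 0 and 0, voom 0 and 0), and for B cells 0 of 1 passed with edgeR (0 higher and 0 lower adjusted over the list alone, 0 higher and 0 lower at an unadjusted p under 0.05, DESeq2 0 and 0, voom 0 and 0). In the knockout, for erythroid markers 0 of 1 passed with edgeR (0 higher and 0 lower adjusted over the list alone, 0 higher and 0 lower at an unadjusted p under 0.05, DESeq2 0 and 0, voom 0 and 0). Xist, from the inactive X chromosome, lay at 317 to 1342 CPM in experiment 1 and at most 0.364 CPM in experiment 2, while the Y-linked Ddx3y was at 0 in all libraries of experiment 1 and lay at 136 to 254 CPM in experiment 2, and Eif2s3y at 0 and at 23.3 to 52.1 CPM. With the replicate block, of sex-linked genes 2 of 4 fell (2 adjusted over the list alone) in the knockout, Eif2s3y and Ddx3y. The experiments differ in these transcripts as well as in stimulus, which bears on every comparison between them.

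Another pattern is that called genes cluster along chromosome 11 in the knockout fitted with the replicate term, while without it no gene of the run passed. Chance placement is argued against: 10000 shuffles of 9480 positioned genes (274 higher and 318 lower) gave a run of 5 with a permutation p = 0.00050, and the data held 2 runs of 4 or more genes. The shuffles treated Sfi1 and Eif4enif1, which overlap and may share reads, as separate genes. A DNA difference between the mouse lines on chromosome 11 cannot be told apart from other causes of the run from Sfi1 to Pik3ip1. Its fold changes showed a heterogeneity p of 0.739 and 0 of 6 tested flanking genes were called in the same direction, but the genes were picked for being called alike and a run ends at a gene not called, so neither value supports it. The labels do not name the origin of the knockout line, and DNA was not analysed here. Loss of itaconate cannot be told apart either: 3 genes of the run, Sfi1, Eif4enif1 and Pik3ip1, were lower with compound plus LPS against LPS, and 0 were called with the compound alone (edgeR). Nnt, which differs between C57BL/6 substrains and was examined after the other values were seen, did not pass (log2 -0.03, adjusted p = 0.98, with the term). Counts from the 3′ end do not read the rest of a transcript, so this value does not decide whether the mouse lines differ in substrain.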
